A study of Homo sapiens with 14 samples.

How the data were processed

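Gene expression was measured in 14 arrays of the human uveal melanoma cell line Mel202, which carries mutations in GNAQ, the gene of a G protein alpha subunit. The cells had been treated with ICG-001 at 3 µM or with DMSO, the solvent, for 24 h or 48 h. Per the labels, total RNA was amplified and biotin-labelled with the Illumina TotalPrep kit and hybridised to Illumina bead arrays.

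The deposited table of non-normalized values gives an intensity, the mean signal of a probe on an array, for 47323 probes. Its lowest values lie well above 0 and its quartiles differ between arrays. Per the file headers, the column beside each signal is the p-value of detection, which falls in steps of 1 in 770 against the negative control probes of the same array. A second table, made by the authors, holds 22579 of these probes on a scale close to log2. In the authors' table every array has the median 7.985 and the 75th percentile 9.13, the mark of values brought to 1 distribution. Its values rank the probes as the signal of the same array does (rank correlation 1), and for bright probes their slope against log2 signal is 0.977 to 1.06. All 20730 probes with a detection p-value below 0.01 on any array are in the authors' table. The package lumi is named in the submitters' processing notes, with no version and no settings. The transformation, background correction, normalization and probe filter behind the authors' table are not given in the sources used here.

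The arrays had median signals of 113.1 to 139.1, and between 13608 and 17374 probes per array (28.8% to 36.7%) had a detection p-value below 0.01. The number of arrays limits the precision of every value.

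The non-normalized signals were background-corrected from their detection p-values, given an offset of 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p-value below 0.05 on at least 3 arrays were kept, which left 22158. The array annotation named 16545 probes by 1 symbol and 3 by several, and 6031 probes of the authors' table had no entry. Of the probes past the filter, 15665 carried 1 symbol and 6493 did not. Symbols were brought up to date through the gene identifiers of a RefSeq table (assembly GRCh38.p14), which was used for names alone and not for positions. For each of the 11679 genes tested, the probe with the highest mean log2 value stood for the gene. For 3142 of these genes more than 1 probe was past the filter.

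Arrays whose titles share a number and differ in the letter a or b were averaged to 1 replicate, because nothing in the labels says that they come from separate cultures. This left 10 replicates, with n = 2 for DMSO and n = 3 for ICG-001 at each time. Within these pairs of arrays, limma estimated a correlation around the group means of 0.175. It was 0.542 with the title ending b as a term of the model. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. No paired analysis was possible because no number in the titles is shared between groups.

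A means model over all 4 groups was fitted with lmFit and eBayes of limma (residual degrees of freedom 6, prior degrees of freedom 5.16). Its contrasts were ICG-001 against DMSO at 24 h and at 48 h, the mean of these effects, their difference, and DMSO at 48 h against DMSO at 24 h. Every adjusted p for a gene is limma's p with the Benjamini-Hochberg correction over the 11679 genes, with a threshold of 0.05, two-sided. "Rose" and "fell" are used for genes past that threshold. Values are means of log2 signal with the SD between replicates, and log2 changes carry the SE of the fit.

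Gene lists were written before the data were examined, as were the design, the rule for named genes and the alternatives not marked as added later. Of these lists, 37 had at least 3 tested members. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 37 lists of a comparison. Each call was repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Of the marker lists for cell types other than melanoma cells, the fibroblast list had 1 tested gene, LUM, and the endothelial list had 1, EMCN, so neither was tested as a list.

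The rule for named genes took, at 24 h and at 48 h, the 10 largest rises and the 10 largest falls past the threshold in which every ICG-001 replicate lay on 1 side of every DMSO replicate. For the difference of the effects and for DMSO over time it took the 5 largest each way past the threshold. It added up to 4 members with the smallest p of every list past the threshold. It also took CREBBP, EP300, CTNNB1, BIRC5, MYC, CCND1, AXIN2, CDKN1A and MITF in every comparison, whatever their result. Genes named outside it are said to be chosen after their values were seen. Genes that reveal the sex of a donor and probes with no symbol or with several are not named. A group with no array above background on any probe of a gene gives a fold that is a lower bound, computed against the lowest detected level.

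Each result for genes was recomputed with every array as a replicate, with the title number as a random block, without background correction, with an offset of 50, and with 75th percentile scaling. Further alternatives were the authors' table, no detection filter, detection p-values below 0.01 on every array of a group, all probes, trend and robust in eBayes, array weights, a fit to the compared groups alone, and each replicate left out. The lists were recomputed with every array as a replicate, with 75th percentile scaling, in the authors' table, with no detection filter and with each replicate left out, besides the estimated correlation and fry and the analyses of the arrays ending in b. The other alternatives were not run for lists. The mean and the difference of the effects use all 4 groups, so for them a fit to the compared groups is the same fit. Slide or chip as a block was not run because the files give no slide. Leaving out the 4 arrays with titles ending in b, and using that ending as a batch term, were added for genes and lists after the data were seen. The batch term was fitted with every array as a replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

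The fit was tested on simulated data of the same size, with independent genes and 50 genes changed at each fold. At 24 h, 11 of 50 genes changed 1.5-fold, 40 changed 2-fold and 49 changed 3-fold were found. For the difference of the effects these numbers were 1, 24 and 41. Between 3.06% and 7.04% of the calls were false, and 0 of 30 unchanged lists were called by camera. As the simulated genes were independent, this does not show how often camera calls unchanged lists whose genes are correlated.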

Results

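Transcript levels were compared in Mel202 uveal melanoma cells treated with ICG-001, a small molecule that binds the coactivator CBP and blocks its interaction with β-catenin, or with DMSO. The series asks how the compound regulates gene expression in these cells. DMSO was measured on 3 arrays at 24 h and 3 at 48 h, and ICG-001 at 3 µM on 4 arrays at each time. With arrays of a shared title number averaged, n = 2 for DMSO and n = 3 for ICG-001 at each time. Between 17619 and 20124 probes per array had a detection p-value below 0.05. The first principal component of the arrays, with 46.2% of the variance, separated ICG-001 from DMSO. The second, with 15.3%, separated the 4 arrays with titles ending in b, 1 in each group, from the other 10. Of the probes above background, 13840 ± 190 (SD, n = 4) per array were detected at a p-value below 0.01 on the arrays ending in b and 16290 ± 585 (SD, n = 10) on the others (exact permutation p = 0.000999, two-sided, the smallest that 1001 arrangements can give).

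The first comparison asks what ICG-001 changed after 24 h. Most measured genes of the amino acid and ATF4 response rose. ASNS, which makes asparagine, was 8.64-fold higher (log2 change 3.11 ± 0.12 SE, adjusted p = 2.01e-07), at 12.65 ± 0.09 (SD, n = 3) against 9.54 ± 0.04 (SD, n = 2). Of the 25 measured members of this list, 22 rose, 0 fell and 3 did not pass, with 23 higher and 0 lower adjusted over the list alone. Besides ASNS, the members with the smallest p were STC2, a secreted glycoprotein (4.72-fold), DDIT4, an inhibitor of mTORC1 signalling (3.74-fold), and PHGDH, the entry enzyme of serine synthesis (2.94-fold). The list's median log2 change was 0.98 (camera adjusted p = 1.49e-14, and adjusted p = 0.0435 with an estimated correlation).

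Of the 14 measured chaperones of the endoplasmic reticulum, 0 rose, 8 fell and 6 did not pass at 24 h, and adjusted over the list alone 0 rose and 8 fell. CALR, a calcium-binding chaperone, was 2.5-fold lower (log2 change -1.32 ± 0.13 SE, adjusted p = 0.000184). HYOU1 was 2.31-fold lower, SDF2L1 2.19-fold and the disulfide isomerase PDIA6 2.07-fold. The chaperone list's median was -0.62 (camera adjusted p = 0.000273, and adjusted p = 0.371 with an estimated correlation). Of the 35 mitosis genes, 0 rose, 17 fell and 18 did not pass, against 1 higher and 18 lower adjusted over the list alone. The centromeric histone CENPA was 1.94-fold lower, the kinase AURKB 1.92-fold, and the kinetochore protein NUF2 and the spindle factor TPX2 1.87-fold each. The mitosis list's median was -0.38 (camera adjusted p = 8.59e-08, and adjusted p = 0.168 with an estimated correlation). Of the 37 genes of DNA replication, 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a camera adjusted p of 0.98.

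Of the 15 measured targets of YAP and TAZ, 6 rose and 0 fell at 24 h, in both adjustments (adjusted over all genes and adjusted over the list alone). MYOF was 2.97-fold higher, CRIM1 2.03-fold, the matricellular factor CCN2 1.73-fold and FJX1 1.54-fold. The calls of CCN2 and FJX1 ended without the averaged pair of DMSO arrays (adjusted p = 0.0558 and 0.122). The camera adjusted p of this list was 0.0329, against an adjusted p = 0.256 with an estimated correlation and 0.0955 without the arrays ending in b (0.000203 to 0.256 over the alternatives). Among 18 Wnt and β-catenin target genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0611). Among its members MYC, a growth-promoting transcription factor, was 2.08-fold higher (log2 change 1.06 ± 0.20 SE, adjusted p = 0.00456), at 12.56 ± 0.01 (SD, n = 3) against 11.50 ± 0.61 (SD, n = 2). Its log2 change was 0.63 without the averaged DMSO pair and 1.49 without DMSO 24 h replicate 1, and passed in both. AXIN2, a feedback inhibitor of Wnt signalling, was 1.49-fold higher (log2 change 0.58 ± 0.16 SE, adjusted p = 0.0252), and its log2 change was 0.14 in the authors' table (adjusted p = 0.113). Its call also ended without the arrays ending in b, with array weights and with the title number as a block. It ended as well without DMSO 24 h replicate 1 (adjusted p = 0.0658), the averaged DMSO pair (0.118), ICG-001 24 h replicate 4 (0.0765) or the averaged ICG-001 pair (0.0627), over a range of 0.018 to 0.118. TNFRSF19, a receptor of the tumour necrosis factor family, was 3.97-fold higher, and its other probe was not called. CCND1, the cyclin of the G1 phase, had a log2 change of 0.39 ± 0.13 SE and did not pass (adjusted p = 0.0535, and 0.00686 to 0.276 over the alternatives).

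The other fixed genes did not pass at 24 h. The log2 change was 0.67 ± 0.27 SE for CTNNB1, which encodes β-catenin (adjusted p = 0.0912). It was 0.18 for EP300, -0.09 for CREBBP, which encodes CBP, 0.14 for the cell cycle inhibitor CDKN1A, -0.12 for the melanocyte regulator MITF and 0.02 for BIRC5, which encodes survivin (adjusted p from 0.537 to 0.923). Of the 2 other probes of CTNNB1, 1 was called, in the same direction. With every array as a replicate CTNNB1 passed, at a log2 change of 0.85 (adjusted p = 0.00985), and without DMSO 24 h replicate 1 it passed with an adjusted p of 0.00287. Without the averaged DMSO pair its log2 change was 0.09 (adjusted p = 0.787), and without DMSO 24 h replicate 1 it was 1.247, the ends of its range over the alternatives.

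Beyond the lists, the largest rises at 24 h included SCRG1 (7.77-fold), the lipid transporter ABCA3 (5.1-fold), the transcription factor USF1 (4.61-fold), AFMID (4.5-fold), CDC42SE1 (4.45-fold), the pro-apoptotic BCL2-family gene PMAIP1 (4-fold) and the mitochondrial enzyme PCK2 (3.87-fold). The largest falls were in cancer-testis antigens of the GAGE and SSX families. GAGE12B was 5.81-fold lower (log2 change -2.54 ± 0.19 SE, adjusted p = 3.58e-05), GAGE12H 5.71-fold, GAGE12C 5.11-fold, SSX1 4.39-fold, GAGE12E 4-fold and GAGE12F 3.53-fold. YWHAE was 4.08-fold lower, the transcriptional repressor NACC1 3.98-fold, the matrix proteoglycan LUM 3.55-fold and EMP3 3.17-fold. LUM is the single measured gene of the fibroblast marker list, and its other probe was not called at 24 h. Of 5 markers of the retinal pigment epithelium, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.253). Of 3 epithelial markers 1 fell, and of 4 immune markers 1 fell (1 each adjusted over the list alone, camera adjusted p = 0.314 and 0.432). In the authors' table the log2 changes of 18 of 36 named genes that passed at 24 h were over 1.5 times smaller, such as those of ABCA3 (0.76), STC2 (0.92), MYOF (0.58) and CRIM1 (0.26).

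In all, 1602 genes rose and 1231 fell at 24 h of 11679 tested, 160 and 115 of them by at least 2-fold. For 5952 genes (51%) the ICG-001 and DMSO replicates did not overlap, where chance gives 20%. The count of 2833 fell to 1514 without the averaged pair of DMSO arrays, and 4 of 37 lists passed, against 1 with an estimated correlation.

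**Figure D1:**
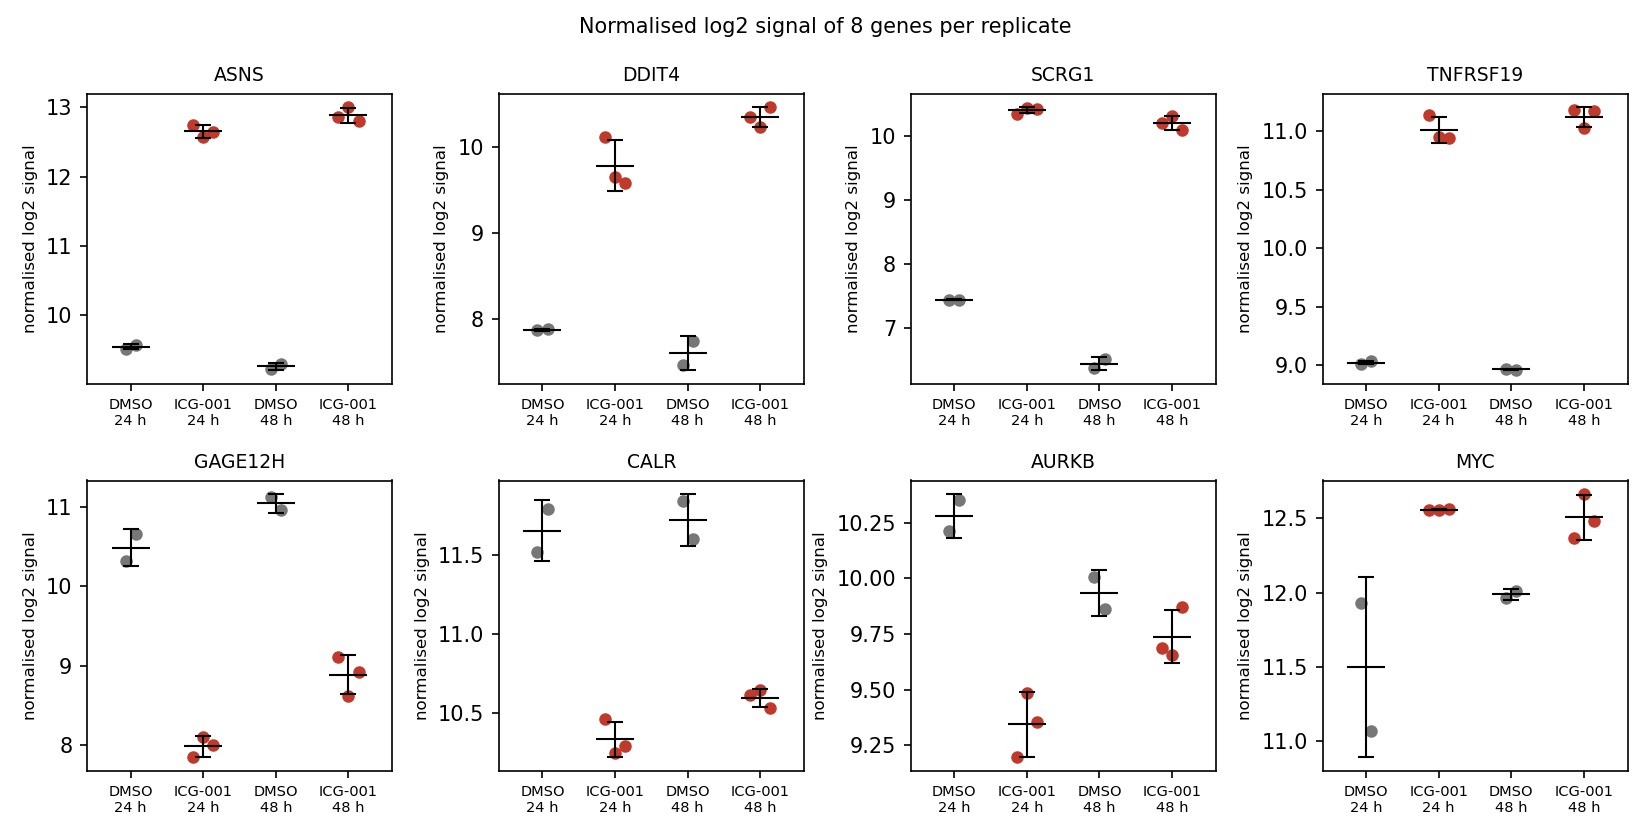
Normalised log2 signal of 8 genes in each replicate, with points for replicates and bars for the group mean ± SD (n = 2 for DMSO and 3 for ICG-001). ASNS lay at 12.65 and 12.89 with ICG-001 at 24 h and 48 h, against 9.54 and 9.26 with DMSO.

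The comparison at 48 h asks the same after the longer treatment. SCRG1, which encodes a small secreted protein, was 13.5-fold higher (log2 change 3.75 ± 0.12 SE, adjusted p = 2.5e-08) and ASNS 12.4-fold (3.63 ± 0.12 SE, adjusted p = 2.5e-08), with n = 3 against n = 2. Of the 25 ATF4 response genes, 22 rose and 0 fell, in both adjustments (22 and 0 adjusted over the list alone). DDIT4 was 6.67-fold higher, STC2 6-fold and PHGDH 3.71-fold. The median log2 change was 1.23 (camera adjusted p = 7.5e-17, and adjusted p = 0.0296 with an estimated correlation). Further large rises were those of CHAC1, which degrades glutathione (6.11-fold), ZCWPW1 (5.49-fold), AFMID (5.17-fold), the potassium channel subunit KCNG1 (4.47-fold) and TNFRSF19 (4.47-fold). ABCA3 was at least 8.32-fold higher, as no DMSO array at 48 h was above background for it.

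Of the 14 endoplasmic reticulum chaperones, 9 fell and 0 rose at 48 h (9 and 0 adjusted over the list alone). CALR and HYOU1 were 2.18-fold lower, PDIA6 2.12-fold and PDIA4 1.84-fold. The list's median was -0.58 (camera adjusted p = 0.000213, and adjusted p = 0.416 with an estimated correlation). Of the 19 pigmentation genes, markers of the melanocyte lineage, 9 fell, 2 rose and 8 did not pass (9 lower and 2 higher adjusted over the list alone). RAB27A, which moves melanosomes, was 2.13-fold lower (log2 change -1.09 ± 0.16 SE, adjusted p = 0.000997), the melanosomal transporter SLC45A2 1.77-fold and the endothelin receptor EDNRB 1.42-fold. The receptor ERBB3 was 1.89-fold higher on the probe with the highest signal, and 1 of its 2 other probes was called in the opposite direction. The list's median was -0.39 (camera adjusted p = 0.0269, and adjusted p = 0.293 with an estimated correlation). Its adjusted p was 0.0553 with 75th percentile scaling and 0.0578 without ICG-001 48 h replicate 1 (0.000726 to 0.293 over the alternatives). Without the averaged pair of DMSO arrays the call of EDNRB ended (adjusted p = 0.0691).

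Of the 35 mitosis genes, 3 rose and 6 fell at 48 h, and the list did not pass (camera adjusted p = 0.174). BIRC5 was 1.44-fold higher (log2 change 0.53 ± 0.13 SE, adjusted p = 0.0135), a call that ended without the averaged DMSO pair of 48 h (adjusted p = 0.0665) or DMSO 48 h replicate 3 (0.0775). Of the 18 Wnt and β-catenin targets, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.225), and of the 15 targets of YAP and TAZ 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0805). The other fixed genes did not pass. Their log2 changes were 0.52 for MYC (adjusted p = 0.0849), 0.34 for AXIN2 (0.144), -0.32 for CREBBP (0.0736), -0.30 for MITF (0.129), 0.19 for CCND1 (0.312), 0.16 for CTNNB1 (0.697), -0.16 for EP300 (0.634) and 0.08 for CDKN1A (0.718). MYC passed under 9 of its 24 alternatives (adjusted p from 0.0107 to 0.252), among them without either DMSO replicate of 24 h. CREBBP passed under 4 (0.0213 to 0.332), and its other probe was called in the opposite direction.

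Among the largest falls at 48 h, LUM was 4.66-fold lower (log2 change -2.22 ± 0.16 SE, adjusted p = 1.56e-05) and HAS2, which makes hyaluronan, 3.95-fold. The kinases MAPK10 and MAP2K6 of the stress-activated pathways were 4.02-fold and 3.52-fold lower. GAGE12H was 4.48-fold lower, GAGE12E 4.11-fold, GAGE12B 3.9-fold and GAGE12C 3.55-fold. NACC1 was 3.73-fold lower and the probe signal of RNU11, a small nuclear RNA of the minor spliceosome, 3.59-fold. Of the 5 retinal pigment epithelium markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone), and 1 of 3 epithelial and 1 of 4 immune markers fell (1 each adjusted over the list alone). None of these marker lists passed with camera at 48 h. In the authors' table the log2 changes of 16 of 30 named genes that passed at 48 h were over 1.5 times smaller, such as those of SCRG1 (2.38), ABCA3 (1.18), CHAC1 (0.91) and HAS2 (-0.61).

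In all, 1640 genes rose and 1370 fell at 48 h, 205 and 158 of them by at least 2-fold, and for 6354 genes (54.4%) the groups did not overlap, where chance gives 20%. The count of 3010 fell to 1398 without the averaged pair of DMSO arrays and to 1739 without DMSO 48 h replicate 3. Of 37 lists 3 passed, against 1 with an estimated correlation.

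**Figure D2:**
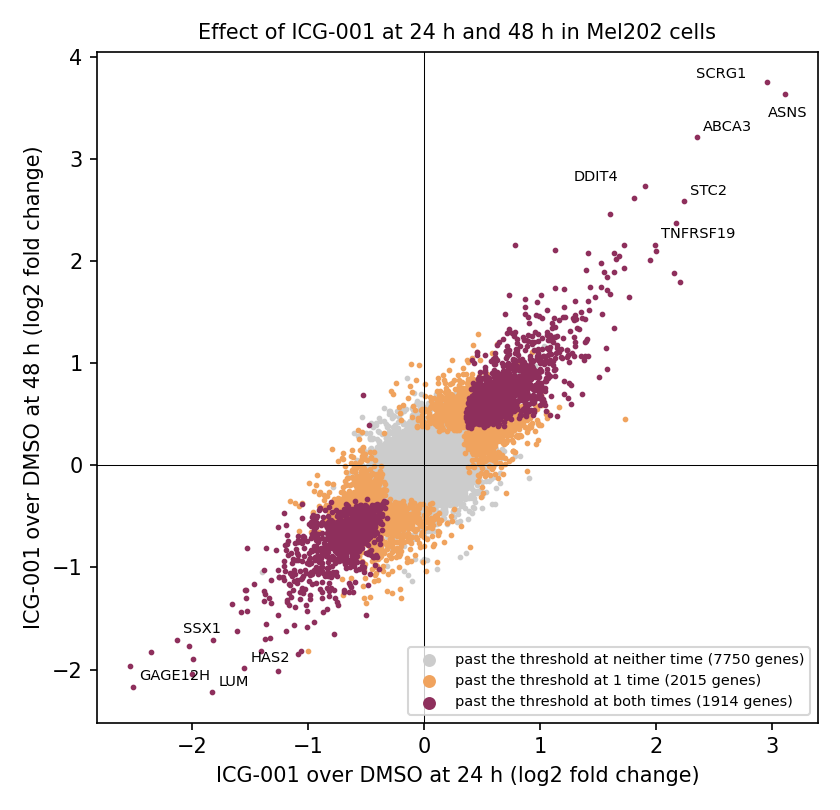
Log2 fold change of each of 11679 genes with ICG-001 over DMSO at 24 h (horizontal) and 48 h (vertical), coloured by whether the gene passed the threshold at neither time, at 1 time or at both. Of the genes, 1914 passed at both times, and ASNS and SCRG1 lie farthest to the upper right.

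The mean of the effects at 24 h and 48 h describes what ICG-001 changed over both times, with 6 ICG-001 against 4 DMSO replicates. ASNS was 10.3-fold higher (log2 change 3.37 ± 0.08 SE, adjusted p = 1.23e-09), STC2 5.32-fold, DDIT4 4.99-fold and PHGDH 3.3-fold. Of the 25 ATF4 response genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 2.01e-14, and adjusted p = 0.0445 with an estimated correlation). Of the 14 chaperones 9 fell and 0 rose (10 lower and 2 higher adjusted over the list alone). CALR was 2.33-fold lower, HYOU1 2.24-fold, PDIA6 2.09-fold and SDF2L1 2.04-fold (camera adjusted p = 0.000232, and adjusted p = 0.382 with an estimated correlation).

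Of the 35 mitosis genes, 18 fell and 2 rose in the mean effect (19 and 3 adjusted over the list alone). CENPA was 1.69-fold lower, and TPX2 and the kinesin KIF20A 1.58-fold, while the kinetochore protein CENPF was 1.52-fold higher. The list had a camera adjusted p = 0.000232, and adjusted p = 0.292 with an estimated correlation. Of the 19 pigmentation genes, 10 fell and 2 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.0335, and adjusted p = 0.268 with an estimated correlation). RAB27A was 1.93-fold lower, SLC45A2 1.78-fold and EDNRB 1.45-fold, and ERBB3 was 1.88-fold higher with 2 other probes called in the opposite direction. This list's call ended with 75th percentile scaling (adjusted p = 0.0577) and without DMSO 24 h replicate 1 (0.0548) or ICG-001 48 h replicate 1 (0.0511), over a range of 0.000271 to 0.268. Of the 15 targets of YAP and TAZ, 7 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0335, and adjusted p = 0.268 with an estimated correlation). MYOF was 2.56-fold higher, CRIM1 2.07-fold, CCN2 1.63-fold and FJX1 1.5-fold. Without the arrays ending in b this list had an adjusted p of 0.0728. In the authors' table the mean effects of 7 of 24 named genes that passed were over 1.5 times smaller on the log2 scale, among them STC2 (1.03), HYOU1 (-0.66), MYOF (0.46) and CRIM1 (0.26).

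Wnt and β-catenin target genes did not pass as a list in the mean effect (camera adjusted p = 0.103), although 9 of 18 rose and 1 fell (9 and 2 adjusted over the list alone). MYC was 1.73-fold higher (log2 change 0.79 ± 0.14 SE, adjusted p = 0.00139), AXIN2 1.38-fold (adjusted p = 0.00796), CCND1 1.22-fold (adjusted p = 0.0279) and BIRC5 1.21-fold (adjusted p = 0.0332). The log2 changes of the rest were 0.41 for CTNNB1 (adjusted p = 0.101), -0.21 for CREBBP (0.0745), -0.21 for MITF (0.104), 0.11 for CDKN1A (0.427) and 0.01 for EP300 (0.951). The log2 change of AXIN2 was 0.462 in the main fit, 0.281 with the plain subtraction and 0.278 with an offset of 50. In the authors' table it was 0.111, and the call of AXIN2 ended (adjusted p = 0.0524). Leaving out 1 replicate ended that of CCND1 for 4 replicates and that of BIRC5 for 7 (adjusted p up to 0.108 and 0.124). The call of CCND1 also ended with 75th percentile scaling (adjusted p = 0.0645) and that of BIRC5 among all probes (0.0504). Without the averaged DMSO pair of 24 h the log2 change of BIRC5 was 0.18, against 0.275 with all replicates. That of CTNNB1 ran from 0.126 to 0.704 over its alternatives. CTNNB1 passed under 4 of its 23 alternatives (adjusted p from 0.00154 to 0.443 over all), among them without DMSO 24 h replicate 1, where its log2 change was 0.70. CREBBP passed under 4 (0.0217 to 0.227), among them without DMSO 24 h replicate 1 (0.048), and its other probe was called in the opposite direction. MITF passed in the authors' table (0.0433) and without the averaged DMSO pair of 24 h (0.0196). In all, 2641 genes rose and 2237 fell, 167 and 110 of them by at least 2-fold. Of 37 lists 5 passed, against 1 with an estimated correlation, and 5 of 100 splits of the replicates gave at least as many lists.

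The effects at both times overlapped. Of 1602 genes that rose at 24 h and 1640 that rose at 48 h, 1100 were shared, where 225 would be shared if the calls were independent. Of 1231 and 1370 genes that fell, 812 were shared, where 144 would be. Of the 2833 genes that passed at 24 h, 2774 (97.9%) had the same sign at 48 h, and 2 that fell at 24 h rose at 48 h. Across genes, which are not independent replicates, the log2 changes at both times had a Pearson correlation of 0.814 and a Spearman correlation of 0.773.

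The difference of the effects asks whether the response to ICG-001 moved between 24 h and 48 h. Genes of mitosis were less reduced at 48 h as a list, with a median difference of 0.29 on the log2 scale over 35 genes (camera adjusted p = 9.77e-10, and adjusted p = 0.186 with an estimated correlation). Relative to all DMSO replicates, the list's mean was -0.46 ± 0.06 (SD, n = 3) with ICG-001 at 24 h and -0.08 ± 0.01 (SD, n = 3) at 48 h. With DMSO it was -0.04 ± 0.10 (SD, n = 2) and 0.04 ± 0.01 (SD, n = 2). The members with the smallest p had differences of 0.81 ± 0.21 SE for the kinase PLK1, 0.74 for AURKB, 0.65 for NUF2 and 0.51 for BIRC5, and none passed over all genes (adjusted p from 0.869 to 0.874), while 2 members were higher adjusted over the list alone.

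The ATF4 response was larger at 48 h as a list, with a median difference of 0.28 (camera adjusted p = 0.000228, and adjusted p = 0.391 with an estimated correlation). Its members DDIT4, DDIT3, a transcription factor of the stress response, and ASNS had differences of 0.83, 0.81 and 0.52, and the lipoprotein receptor VLDLR had -0.62. The 11 genes of fatty acid synthesis had a median difference of -0.26 (camera adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation). Relative to all DMSO replicates, this list's mean was -0.07 ± 0.15 (SD, n = 3) and -0.05 ± 0.09 (SD, n = 3) with ICG-001 at 24 h and 48 h, and -0.15 ± 0.20 (SD, n = 2) and 0.15 ± 0.10 (SD, n = 2) with DMSO, so the larger move was in the DMSO groups. Among them the desaturase gene FADS1 had -0.47, the regulator SREBF1 -0.46 and the elongase ELOVL5 -0.32. The fatty acid list did not pass without any of 4 replicates, among them the averaged DMSO pair of 24 h (adjusted p = 0.389, and 0.000847 to 0.71 over the alternatives). No member of either list passed over all genes (adjusted p from 0.869 to 0.906).

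For single genes, limma called 0 differences of the 11679 tested, and 660 (5.65%) had an unadjusted p below 0.05, where 584 would by chance. The fixed genes had log2 differences of -0.54 for MYC, -0.51 for CTNNB1, -0.34 for EP300, -0.24 for AXIN2, -0.23 for CREBBP, -0.19 for CCND1, -0.18 for MITF and -0.05 for CDKN1A (adjusted p from 0.876 to 0.992). Simulated 2-fold differences were found for 24 of 50 genes, so smaller differences were mostly not detectable. Of 37 lists 3 passed with camera, against 0 with an estimated correlation and 0 with fry.

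**Figure D3:**
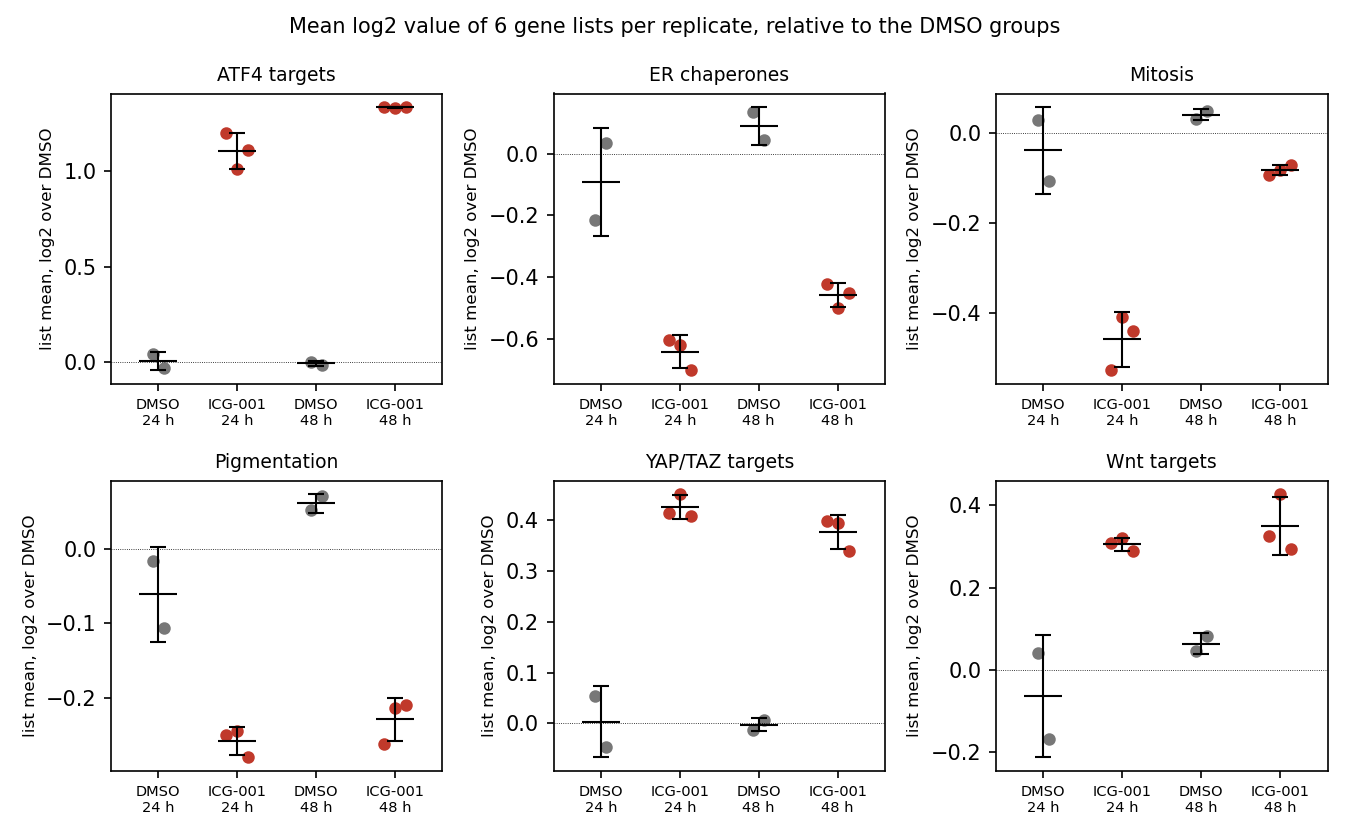
Mean log2 value of 6 gene lists in each replicate relative to the mean of the DMSO groups, with points for replicates and bars for the group mean ± SD (n = 2 for DMSO and 3 for ICG-001). The mitosis list lay at -0.46 with ICG-001 at 24 h and at -0.08 at 48 h, and the ATF4 list at 1.11 and 1.33.

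DMSO at 48 h against DMSO at 24 h compares cells without the compound over time in culture, with n = 2 against n = 2. No array batch is given, and a batch that went with time could not be told apart from it. MGP, an inhibitor of calcification, was 2.4-fold lower at 48 h (log2 change -1.26 ± 0.14 SE), the small heat shock protein CRYAB 2.27-fold and SCRG1 2-fold. SNX10, a sorting nexin, was 2.05-fold higher (all with adjusted p = 0.0235). These 4 genes, 1 higher and 3 lower, were all that passed, and in the same fit 961 genes (8.23%) had an unadjusted p below 0.05. With array weights limma called 0 genes (685 at an unadjusted p below 0.05), and with a fit to the DMSO groups alone 0 (560). In the authors' table the log2 change of SCRG1 was -0.415 and did not pass (adjusted p = 0.105), and that of SNX10 was 0.586. Without DMSO 24 h replicate 1 the count was 42, and without any of 6 other replicates it was 0.

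As lists, 11 genes of fatty acid synthesis were higher at 48 h in DMSO, with a median of 0.30 (camera adjusted p = 0.00069, and adjusted p = 0.429 with an estimated correlation), and the 14 endoplasmic reticulum chaperones were higher, with a median of 0.16 (0.0225, and adjusted p = 0.453 with an estimated correlation). The 3 measured metallothioneins, which bind metal ions, were lower, with a median of -0.50 (0.018, and adjusted p = 0.419 with an estimated correlation). With fry the adjusted p was 0.236 for fatty acid synthesis and 0.244 for the chaperones. No member of the 3 lists passed over all genes, and adjusted over the list alone 2 metallothioneins did. Without the averaged DMSO pair of 24 h the adjusted p was 0.263 for fatty acid synthesis and 0.29 for metallothioneins, and without DMSO 24 h replicate 1 it was 0.874 for the chaperones. Without the averaged DMSO pair of 48 h it was 0.301 for the chaperones and 0.126 for metallothioneins. The chaperones also did not pass with 75th percentile scaling (adjusted p = 0.0957, median 0.07), without the arrays ending in b (0.0638) or with that ending as a batch term (0.0604). The log2 change was 0.53 for ELOVL5, 0.44 for the chaperone DNAJB9 and -0.50 for MT1X (adjusted p from 0.467 to 0.57). FADS2 was not above background on any DMSO array at 24 h, and its fold, at least 1.35, did not pass. The fixed genes had log2 changes from 0.01 for CDKN1A to 0.56 for EP300 (adjusted p from 0.578 to 0.998).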

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

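The tests of a single replicate, of the DMSO cells alone, of the order of the time labels and of dimmer arrays were chosen after the results were seen. So were the analyses without the arrays ending in b.

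The array ICG-001 24 h replicate 2 had 14060 probes with a detection p-value below 0.01, against 15933 to 16009 on the other arrays of its group. Its gap to the nearest array was 0.961 of the group's range, above the limit of Dixon's test at the 95% level for 4 arrays. Of 10 combinations of a group and a measure, this was the 1 past its limit, and chance alone passes about 1 in 20.

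That array is 1 of 4 with a title ending in b, and all 4 had fewer probes above background than the other arrays, with 13608 to 14060 against 15294 to 17374. The signals of their negative controls, as read from the detection p-values, were wider, at 28.8 against 16.5 (exact permutation p = 0.000999, two-sided, the smallest possible). A wider background is a candidate explanation of the lower number. The width is read from the same p-values that define that number, so it is no separate test. On the arrays ending in b the 75th percentile signal was 203 against 195 (exact permutation p = 0.559). In each of the 4 groups other arrays were dimmer than the array ending in b, 7 in all, yet had at least 15294 probes detected, which argues against dimmer arrays as the whole cause. Each group holds 1 such array, and no biological explanation was tested.

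The mitosis list differed between the effect at 24 h and at 48 h (camera adjusted p = 9.77e-10), with a change of the list mean of 0.296 (log2, SE 0.069). The change was 0.304 (SE 0.074) without the arrays ending in b, at least 0.238 (SE 0.058) in the authors' table and with 75th percentile scaling, and 0.227 (SE 0.058) without DMSO 24 h replicate 1, where it was lowest for its SE, which argues against these arrays, the scaling or 1 replicate as the whole cause. A drift in the DMSO cells alone is argued against by the change between times within ICG-001, which was 0.375 (SE 0.044). The exact permutation p for the order of the time labels was 0.1, two-sided over 120 arrangements. The list means of the ICG-001 replicates were already fully apart, at -0.526 to -0.408 at 24 h and -0.093 to -0.072 at 48 h. With so few replicates the test had little room for a smaller p. It therefore cannot decide, and chance in the order of the time labels stays open. A weaker effect on mitosis genes at 48 h than at 24 h may be followed up as a hypothesis, as the call is also lost with an estimated correlation (adjusted p = 0.186).

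The ATF4 response differed between the effects at 24 h and 48 h with a camera adjusted p of 0.000228, and with an adjusted p = 0.391 with an estimated correlation. Fatty acid synthesis differed between them with a camera adjusted p of 0.011, and with an adjusted p = 0.71 with an estimated correlation.

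Of the 6493 probes past the filter that the annotation gives no single gene symbol, which the comparisons of genes do not use, 1404 passed the threshold for the mean effect of ICG-001, 690 higher and 714 lower.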

How the results depend on the processing

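The analyses without the arrays ending in b and with that ending as a batch term were chosen after the data were seen. Apart from the fixed genes, the named genes were picked from these same data for large changes or small p. How often their calls held therefore does not describe genes in general. Of 154 results for named genes, 94 passed the threshold. Of these, 86 did so under every alternative that left no replicate out and 83 without any 1 replicate. Of the 60 that did not pass, 52 did not under every alternative that left no replicate out, and 0 passing results changed sign. The cause was not tested for any of the shifts below, except that all probes and fewer replicates change what is tested.

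For genes, the 4 calls in DMSO over time became 29 with every array as a replicate and 17 with the title number as a block. They were 10 with the plain subtraction, 12 with an offset of 50, 2 among all probes and 9 with trend and robust. They became 0 with array weights, 0 with the DMSO groups alone and 1 without the arrays ending in b. With that ending as a batch term and every array as a replicate they became 96. The fit with that batch term gave 4581 calls at 24 h and 4518 at 48 h, against 2833 and 3010. As it also took every array as a replicate, these shifts cannot be put down to the batch term alone. The mean effect had 7355 calls among all probes, against 4878 genes. With 1 replicate left out, the counts ranged from 1514 to 2692 at 24 h, from 1398 to 3305 at 48 h, from 3855 to 4601 for the mean, from 0 to 1 for the difference and from 0 to 42 for DMSO over time. Where a group was left with 1 sample, that sample was assumed to vary like the other groups.

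For lists, the estimated correlation left 1 at 24 h, 1 at 48 h, 1 for the mean, 0 for the difference and 0 for DMSO over time, against 4, 3, 5, 3 and 3. With fry 18, 17, 23, 0 and 2 passed, in the same order. For DMSO over time 6 passed with every array as a replicate and 6 with 75th percentile scaling. For the difference 5 passed with 75th percentile scaling, 5 in the authors' table and 5 without the arrays ending in b, and at 48 h 5 passed in the authors' table. With 1 replicate left out, 4 to 7 passed at 24 h, 2 to 4 at 48 h, 4 to 6 for the mean, 2 to 4 for the difference and 1 to 3 for DMSO over time. Signal over background limits ABCA3, not detected with DMSO at 48 h, and FADS2, not detected with DMSO at 24 h. Other named genes had low signal as well. With DMSO at 24 h AXIN2 lay at 5.27, AFMID at 5.53 and STC2 at 5.78, against 5.08 for ABCA3. GAGE12F lay at 5.44 with ICG-001 at 24 h.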

Other observations

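The gene families below, the analysis without the arrays ending in b, the test of different transcripts and that of the synthetases were chosen after the values were seen, and the test of the synthetases was narrowed to genes outside the ATF4 list after a first result on all of them.

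Most cancer-testis antigens measured, a family chosen after its members stood out among the largest falls, fell with ICG-001. In the mean of the effects at 24 h and 48 h, 18 of 22 genes fell, 1 rose and 3 did not pass, with a median fold of 2.12 lower (camera adjusted p = 2.94e-11 over 5 families, and adjusted p = 0.0546 with an estimated correlation). The members that prompted the choice are among the 22, so these p-values in part restate it. GAGE12H was 5.06-fold lower, GAGE12B 4.76-fold, SSX1 3.78-fold and PRAME, a repressor of retinoic acid signalling, 1.32-fold, while MAGEA6 was 1.33-fold higher. The median log2 change lay between -1.11 and -0.41 under the scalings tried. GAGE transcripts are close in sequence, and whether their probes are separate measurements was not tested.

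Of 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 rose, 0 fell and 4 did not pass in the mean effect, with a median of 1.7-fold (camera adjusted p = 2.19e-08, and adjusted p = 0.0546 with an estimated correlation). WARS1 was 2.51-fold higher, EPRS1 2.46-fold and SARS1 2.38-fold, with n = 6 against n = 4 replicates. Of 15 mitochondrial synthetases 6 rose and 4 fell, and under the scalings tried the medians lay between 0.71 and 0.76 for the cytosolic and between 0.07 and 0.16 for the mitochondrial genes. The 16 cytosolic genes outside the ATF4 list had a median log2 change of 0.73 against 0.16 for the mitochondrial genes (permutation p = 0.00654 over 31 genes, two-sided, where genes are not independent). This comparison restates the difference that prompted it, and whether these genes move with the ATF4 response was not tested.

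Of 149 small nuclear, nucleolar and other small RNAs, 59 fell, 4 rose and the rest did not pass in the mean effect, with a median of 1.22-fold lower (camera adjusted p = 2.19e-08, and adjusted p = 0.113 with an estimated correlation). The probe signal of RNU11 was 2.77-fold lower and that of the Y RNA gene RNY5 2.71-fold. Whether the probes of this family measure the mature small RNAs after the labelling used was not tested. The median log2 change lay between -0.29 and -0.08 under the scalings tried. Of 23 histone genes 4 rose and 8 fell (camera adjusted p = 0.315), with a median whose sign changed with the scaling.

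Of 747 genes with at least 2 probes past the threshold for the mean effect, 147 (19.7%) had probes that moved in opposite directions, among them NFIC, TFAP2A and ERBB3. The share was 16.5% (95% interval 13.2% to 20.3%) for probes detected on all 14 arrays and 20.7% (17.7% to 23.8%) without the arrays ending in b, which argues against dim probes or those arrays as the whole cause. It was 19.9% (17.2% to 22.8%) in the authors' table. That table is also brought to 1 distribution and its background correction is not given. It therefore does not test the scaling, and shows only that the share held under the authors' processing. The splits of the replicates within times do not test this count: 1 of 100, the real one, gave as many, but of the others 1 alone had any genes with at least 2 called probes, 3 of them, so their counts were all but fixed at 0. Probes of different transcripts stay open. This was tested among genes with exactly 2 called probes. Of these, 48 of 116 with opposite probes (41.4%) and 177 of 520 with probes moving together (34%) had probes with different transcript identifiers (odds ratio 1.37, 0.884 to 2.1, Fisher's exact p = 0.162, two-sided). No biological explanation was tested.

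For the mean effect, 1 of 100 splits of the replicates within times, the real one, gave as many as 4878 genes, and the highest other gave 10. A split that mixes ICG-001 and DMSO replicates adds their difference to the spread within groups, which holds its count low. The gap between the counts is therefore no measure of chance. As 1 in 100 is the least that these splits can give, chance is not excluded. For the ATF4 response 1 of 100 splits, again the real one, gave a camera p as small as 5.42e-16, and the smallest other was 1.6e-12. Some other splits keep part of the real grouping, and 1 in 100 is again the least possible, so chance is not excluded there either. Nor is it excluded for the count of 5 lists, since 5 of 100 splits gave at least as many and the highest other gave 6.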
